A study of Rattus norvegicus with 30 samples.

How the data were processed

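Gene expression was measured on 30 two-colour cDNA arrays of Sprague-Dawley rats, an outbred laboratory strain. Per the labels, rats were restrained for 50 min, went through nociceptive testing (tests of responses to painful stimuli) and were killed 1 h or 24 h after returning to their home cages. The tissues were the arcuate nucleus of the hypothalamus (Arc), the periaqueductal gray of the midbrain (PAG) and the dorsal horn of the fifth and sixth lumbar segments of the spinal cord (DH). Each of the 6 groups of region and time held 5 arrays, 1 per stressed rat. RNA of the stressed rat was labelled with Cy3, and a pool of RNA from 5 unstressed control rats of the same region was labelled with Cy5 on every array. For every array the labels describe 2 labelling protocols, reverse transcription with Superscript II and oligo(dT) primers and a kit for linear amplification with a T7 primer, and which of them was used is not given in the sources used here. Dyes were not swapped, so a dye bias of a spot cannot be separated from a difference between stressed rats and the pool. Whether the arrays of both times used the same pool is not given in the sources used here. A pool counts as 1 control sample, and the tests leave out the spread between control rats.

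The deposited intensity values are mean scanner brightness per spot and channel with a local background, not normalized, per the file headers, which name ImaGene 5.1 (the labels name ImaGene 4.2). The deposited ratio values in the authors' value table are linear Cy3 over Cy5 ratios, as a comparison with the scanner values of the same arrays showed. Log2 values of its 30 columns correlated with the background-subtracted scanner log ratios at 0.642 to 0.918 across spots, all positive, and column medians were 0.967 to 1.03. Its exact normalization is not given in the sources used here. The table was used only as an alternative. Each array had 12206 spots in 48 print blocks (12 rows and 4 columns of blocks). Spots carry only a position (block row, block column, row, column), the files do not pair positions with genes, and 0 of the positions matched the reference gene table. Results are therefore given by spot, and the gene lists and cell type markers fixed before the data were examined could not be tested. The software's other numerical column, a flag, marked 0 to 321 spots per array as poor, and these were left out, while spots it marked as empty (1.17% to 18.2% per array) were kept and left to the filter on dim spots. A spot counted as saturated where the median of its pixels reached 65000 units in a channel.

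Intensities were background corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0). Values are log2 of stressed rat over control pool. A spot was tested if its mean signal exceeded the local background mean by more than 2 background SD in either channel on at least 5 of the 30 arrays. 12183 spots passed and 23 did not. limma's lmFit and eBayes fitted 6 group means over all 30 arrays with a shared estimate of the spread (prior degrees of freedom 7.43), and a spot was called at a Benjamini-Hochberg adjusted p below 0.05. The tests were each group against 0, 24 h against 1 h in each region, and moderated F tests on 2 degrees of freedom for differences between regions at each time and for the region by time interaction. Simulated arrays with the real spreads, over 9912 spots with values on all arrays, were used to test the fits. The simulated noise was independent between spots and arrays. It held no error of the pool, trend over print blocks, effect of day or dye bias, so the shares below leave these out. For DH at 1 h against the pool, 40.3% of spots changed by 0.25 (log2), 92.5% of those changed by 0.5 and all 66 of those changed by 1 were recovered. For PAG at 24 h against 1 h the shares were 5.97%, 62.7% and 97%. For the region test at 1 h they were 5.97%, 65.7% and 100%, and for the interaction 0%, 32.8% and 87.9%.

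The spots to describe followed a rule fixed before the data were examined, with its requirement of a gene symbol dropped because there are no symbols. For each comparison with the pool they were the 8 highest and 8 lowest called spots above background on all 5 arrays in Cy3 or in Cy5, with 1 sign on all 5 arrays. For 24 h against 1 h they were the 6 highest and 6 lowest called spots whose groups of 5 did not overlap, and for the region tests the 6 lowest adjusted p. Of these, 2 rising and 2 falling positions are printed, those on most of the lists, with ties broken by mean size, a choice made after the data were examined. Single-channel levels were taken after quantile normalization of the mean log intensity between arrays (Aquantile). Changes of a channel between times were set against a running median over 201 uncalled spots of like brightness. Where 2 comparisons shared a nominal pool, 100 simulated pairs of unchanged groups against 1 pool gave the correlation without effects, with the pool given the spread of the 5 rats' mean. That assumed spread by itself fixes the simulated correlation.

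Per the file headers the 30 images were quantified on 6 days, here lettered A to F. Day A held all Arc 1 h arrays and 3 PAG 1 h arrays, day B the other 2 PAG 1 h and all DH 1 h arrays, days C and D the Arc 24 h arrays, day E all PAG 24 h and 2 DH 24 h arrays, and day F the other 3 DH 24 h arrays. The 2 times shared no day. The number of arrays limits the precision. The median standard error was 0.08 (log2) for a group mean and 0.12 for a difference between times.

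Alternatives fixed before the data were examined were no background subtraction, median centring in place of loess, Aquantile, no filter on dim spots, the authors' value table (at spots with enough values in it), a replicate block, quantification day as a random block, leaving out each replicate in turn and, against the pool, a standard error enlarged to give the pool a spread of its own. Per the labels the regions of a group came from the same 5 rats, and the labels do not say that a replicate number marks a rat. Deviations of same-numbered arrays from their group means correlated over 0.1 in all 5 pairs of Arc and PAG at 1 h (0.14 to 0.229), so these groups were also compared with the number as a block, and in at most 4 of 5 pairs elsewhere. That block, a loess within print blocks (span 0.4), day as a fixed block and, for the times and regions, a separate pool for each group with a spread of its own were added after the data were examined.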

Results

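The data were 30 two-colour arrays that set RNA of a single stressed rat, in Cy3, against a pool of 5 unstressed control rats of the same region, in Cy5. They covered the arcuate nucleus (Arc), the periaqueductal gray (PAG) and the lumbar dorsal horn (DH), with 5 rats per region at 1 h and at 24 h after restraint and nociceptive testing. The median spot signal per array was 396 to 1267 units in Cy3 and 374 to 1092 units in Cy5, over median local backgrounds of 69.2 to 128 and 55.9 to 118 units. At least 90.6% of spots per array exceeded background in Cy3 and at least 82.4% in Cy5. After normalization the SD of the log2 ratio over spots averaged 0.23 ± 0.02 (SD, n = 5 arrays) in Arc at 1 h, 0.26 ± 0.01 in PAG and 0.24 ± 0.02 in DH. At 24 h it was wider, at 0.32 ± 0.06 in Arc, 0.35 ± 0.06 in PAG and 0.29 ± 0.04 in DH. Correlations between arrays across spots had a median of 0.441 within groups and of 0.238 between groups, with ranges of -0.00375 to 0.727 and -0.271 to 0.61. The files name spots by position only, so the identity of the genes was not analysed here.

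The first question was which transcripts differed from unstressed rats 1 h after the restraint and testing. Ratios moved in both directions in each of the 3 regions, mostly by less than 1.5-fold. In Arc limma called 1158 of 12183 spots, of which 626 were higher than the pool and the others lower, and 21 higher and 12 lower spots passed 1.5-fold. In PAG 678 spots rose and 512 fell, with 22 and 23 past 1.5-fold. In DH 1109 rose and 810 fell, with 63 and 21 past 1.5-fold. The median size of a called change was 0.32 (log2) in Arc, 0.31 in PAG and 0.31 in DH.

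Spot Sr11Sc02R12C12 was the highest in Arc and in PAG and the second highest in DH among the spots taken by the fixed rule. Its log2 ratio was 1.00 ± 0.26 (SD, n = 5) in Arc, 0.97 ± 0.24 in PAG and 0.96 ± 0.23 in DH, and it was positive on all 15 arrays at 1 h. The limma adjusted p (Benjamini-Hochberg) was 3.11e-06 in Arc, 3.22e-06 in PAG and 9.54e-07 in DH. The 8 highest spots of each region ranged from 0.68 to 1.00 in Arc, 0.68 to 0.97 in PAG and 0.78 to 0.98 in DH. The 8 lowest ranged from -0.68 to -0.60, from -1.07 to -0.78 and from -0.99 to -0.71. In Arc the 8 lowest lay near one end of the 12 block rows and most of the 8 highest near the other. A total of 173 spots were called higher in all 3 regions at 1 h and 43 lower, where independent lists of these lengths would share 3.17 and 1.49. Dyes were not swapped on any array, so these counts cannot be separated from dye bias. Across spots the effects correlated at 0.566 between Arc and PAG, 0.373 between Arc and DH and 0.523 between PAG and DH, and spots are not independent replicates. Print block explained 23.7% of the variance of these effects in Arc, 15% in PAG and 6.45% in DH. After a loess within print blocks, 457 of the 1158 Arc calls, 652 of the 1190 PAG calls and 1477 of the 1919 DH calls were called again. Part of these extremes and correlations may therefore follow position on the array.

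With a spread for the pool as large as that of the mean of 5 stressed rats, limma called 4 spots in Arc at 1 h, 37 in PAG and 288 in DH, and with quantification day as a random block it called 200, 541 and 765. The Arc count was 1768 in the authors' value table and 619 with a loess within print blocks, the PAG count was 1826 in that table, and counts fell by over 1.5 times without Arc replicates 1 (562), 2 (526) or 4 (650), PAG replicates 1 (600) or 2 (561) and DH replicates 3 (1144) or 5 (1266).

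The balance of directions at 1 h depended on the scaling. With median centring in place of loess, 41.1% of Arc calls, 77.9% of PAG calls and 76.7% of DH calls were higher, against 54.1%, 57% and 57.8%.

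At 24 h more spots differed from the pool than at 1 h in Arc and in PAG. In DH the order depended on the processing, with 2171 calls at 24 h and 1919 at 1 h, but 1925 and 2339 without background subtraction, 1582 and 1955 with median centring and 1766 and 2698 in the authors' value table. In Arc 2074 spots were higher and 2007 lower, in PAG 2615 and 2369, and in DH 1216 and 955, by the same limma test. In the authors' value table the balance in PAG turned, with 2346 higher and 2736 lower, as it did in Arc without background subtraction, with 2164 and 2207. With median centring 2761 were higher and 1897 lower in Arc, and 67.7% of the DH calls were higher, against 56%. Higher spots dominated among changes past 1.5-fold, with 233 higher and 58 lower in Arc, 551 and 60 in PAG and 224 and 26 in DH. These strong rises lay mostly in bright spots. The brightest quintile of spots held 170 of the 233 in Arc, 379 of the 551 in PAG and 166 of the 224 in DH, and 39 of the 551 PAG spots reached saturation on at least 1 array.

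**Figure D1:**
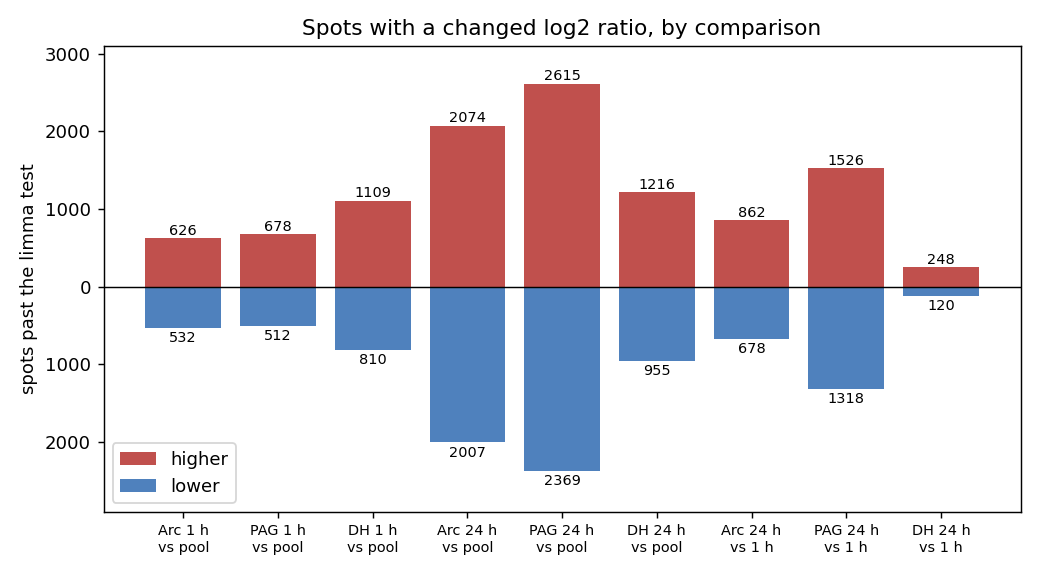
Bars give the number of spots called by limma at each of the 6 group comparisons with the control pool and the 3 comparisons of 24 h with 1 h, upward for higher and downward for lower log2 ratios. PAG at 24 h had the most calls, 2615 higher and 2369 lower, and DH at 24 h against 1 h the fewest, 248 and 120.

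In a set of 129 spots the ratio was over 1.5-fold above the pool in all 3 regions at 24 h, where independent lists would share 0.194. Their median log2 ratio was 0.76 in Arc, 1.24 in PAG and 0.93 in DH at 24 h. At 1 h the medians of the same 129 spots were -0.16, 0.05 and 0.01. Their median Cy3 level was 13.24 at 1 h in each region, and 13.25 in Arc, 13.04 in PAG and 13.20 in DH at 24 h. The Cy5 level was 13.34, 13.32 and 13.17 at 1 h and 12.38, 11.80 and 12.30 at 24 h. Spot Sr01Sc01R14C06 belonged to the highest spots of PAG, at 1.55 ± 0.70 (SD, n = 5), and of DH, at 1.25 ± 0.47. The limma adjusted p was 5.87e-08 in PAG and 1.21e-05 in DH, and the ratio was positive on all 5 arrays of each group. These p rest on a standard error of 0.17 from the spread shared by the 6 groups. At 1 h the SD of this spot was 0.22 in Arc, 0.37 in PAG and 0.30 in DH, so the shared spread may understate that at 24 h. In Arc it was 0.92 ± 0.39, with a limma adjusted p of 2e-04. The 8 highest spots ranged from 1.00 to 1.33 in Arc, 1.54 to 1.73 in PAG and 1.21 to 1.28 in DH. In Arc these 8 all lay in the last of the 4 block columns, and print block explained 16% of the variance of the Arc effects at 24 h. Some of the 8 DH spots were saturated on 1 of the 5 arrays.

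The strongest falls at 24 h were in DH. Spot Sr02Sc01R11C06 had a log2 ratio of -4.35 ± 0.40 (SD, n = 5) in DH at 24 h, with a limma adjusted p of 3.73e-25 and values from -4.78 to -3.87. In the other 5 groups its mean lay between -0.13 and 0.27. The single-channel values placed this difference in the Cy5 channel, where its level was 12.28 on the log2 scale in DH at 24 h and 7.67 in DH at 1 h, while its Cy3 level was 7.93 and 7.61. The 26 DH spots that fell over 1.5-fold had a median of -1.16 in DH at 24 h and of -0.04 in DH at 1 h. Their median Cy5 level was 9.10 in DH at 24 h and 7.68 at 1 h, against Cy3 levels of 7.73 and 7.61. In DH at 1 h 12 of the 26 were above background in Cy3 on all 5 arrays and 11 in Cy5, so many of these levels lay near the background. The 8 lowest spots ranged from -4.35 to -1.34 in DH, from -1.91 to -0.87 in Arc and from -1.92 to -0.85 in PAG. Most of the 8 in Arc lay in row 3 of blocks in the first block column, with SDs of up to 1.64 between the 5 arrays. Spot Sr06Sc03R14C06 was among the lowest in PAG, at -0.85 ± 0.37 (SD, n = 5) with a limma adjusted p of 5.92e-06, and was also lower in Arc, at -0.80 ± 0.43, and in DH, at -0.65 ± 0.40. With the pool given a spread, limma called 1508 spots in Arc, 2616 in PAG and 398 in DH, and with day as a random block 1435 in DH. Without DH replicate 2 the DH count was 1364.

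**Figure D2:**
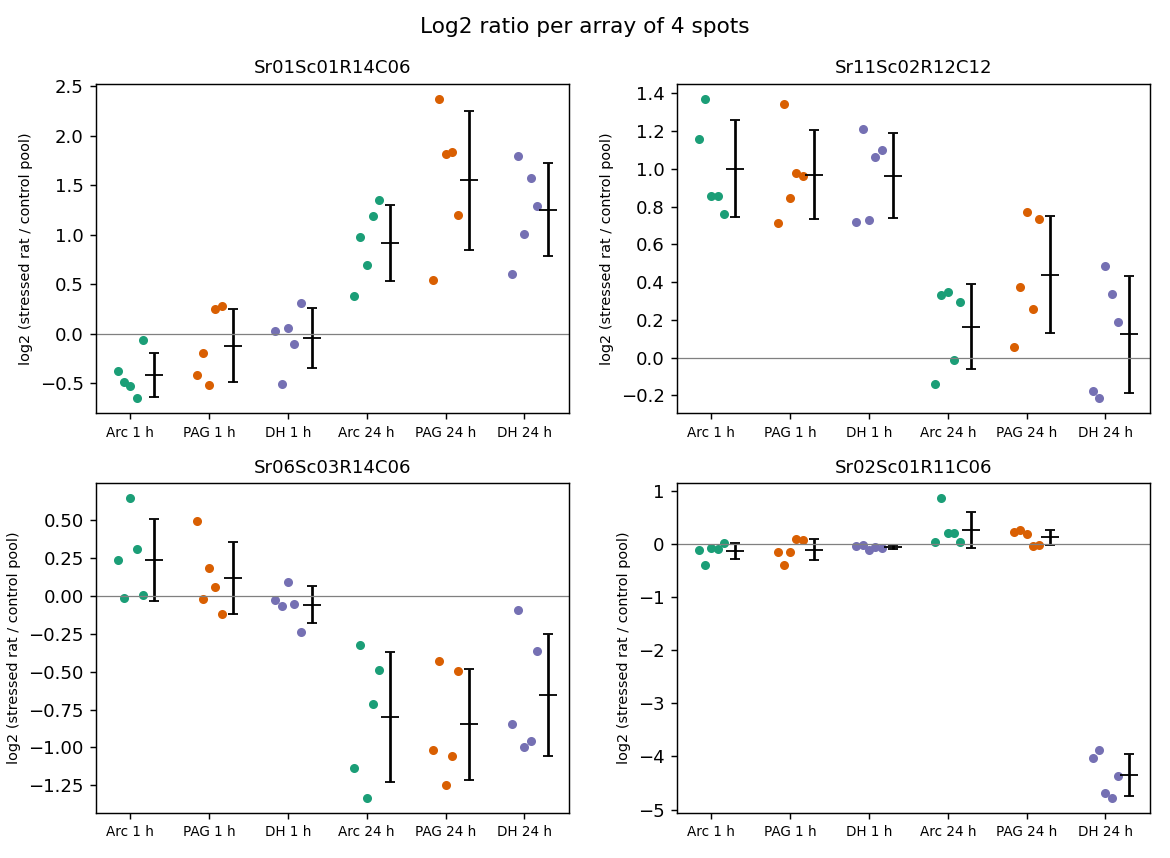
Points are the log2 ratios of stressed rat over control pool on the single arrays of the 6 groups for 4 spots, and the bar beside each group is the mean with its SD (n = 5). Sr11Sc02R12C12 stood near 1 at 1 h in the 3 regions, Sr01Sc01R14C06 was higher and Sr06Sc03R14C06 lower at 24 h, and Sr02Sc01R11C06 left the zero line by more than 1 unit only in DH at 24 h.

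Of 12183 spots, 50 were called higher than the pool in all 6 groups and 6 were called lower, where independent lists would share 0.0116 and 0.00373. Their median ratios ran from 0.37 to 0.54 for the higher set and from -0.43 to -0.25 for the lower set. With no dye swap, these sets cannot be separated from a dye bias common to all arrays. Within a region, the effects at 1 h and at 24 h correlated across spots at 0.284 in Arc, 0.221 in PAG and 0.385 in DH. Unchanged groups simulated against 1 shared pool gave 0.5, 0.5 and 0.499. These values were set in advance by giving the pool the spread of a group mean, so they are no benchmark for the observed correlations. The observed covariances were 0.011, 0.0107 and 0.0149, against 0.0089, 0.00887 and 0.0089 in the simulation, which rest on the same assumed pool spread. In Arc 342 spots were called higher at both times and 136 lower, where independent lists would share 107 and 87.6, and 59 were called in opposite directions. The corresponding counts were 345, 153 and 134 in PAG, with 146 and 99.6 for shared directions in independent lists, and 357, 295 and 8 in DH, with 111 and 63.5. Whether the arrays of both times used the same pool is not given in the sources used here, so it is open how far a shared control adds to these counts.

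The direct comparison of 24 h with 1 h tested which ratios moved between the times. PAG changed at the most spots, 1526 higher and 1318 lower at 24 h, followed by Arc with 862 and 678 and DH with 248 and 120 by limma. Past 1.5-fold there were 545 higher and 86 lower in PAG, 224 and 40 in Arc and 130 and 34 in DH. Print block explained 24.3% of the variance of the changes in Arc, 7.12% in PAG and 4.41% in DH. After a loess within print blocks, 554 of the 1540 Arc calls, 2233 of the 2844 PAG calls and 275 of the 368 DH calls were called again. Part of the Arc changes, and of their overlap with PAG, may therefore follow position on the array. The ratio of spot Sr01Sc01R14C06 was higher at 24 h by 1.34 ± 0.25 (SE) in Arc, 1.67 ± 0.25 in PAG and 1.29 ± 0.25 in DH, with limma adjusted p of 0.00113, 2.61e-05 and 0.00351. Its Cy3 level went from 14.36 to 13.94 in Arc and from 14.56 to 14.01 in DH, and its Cy5 level from 14.77 to 13.02 and from 14.60 to 12.76. In PAG at 1 h it was above background on 4 of the 5 arrays, and from the mean of these 4 Cy3 went from 14.28 to 14.24 and Cy5 from 14.38 to 12.69. Spot Sr06Sc03R14C06 fell by 1.04 ± 0.19 (SE) in Arc and by 0.97 ± 0.19 in PAG, with limma adjusted p of 0.00096 and 0.000395, and its difference in DH was -0.59 ± 0.19 with an adjusted p of 0.0775. Spot Sr11Sc02R12C12, which was high at 1 h, fell by 0.835 ± 0.16 in Arc, by 0.53 ± 0.16 in PAG and by 0.84 ± 0.16 in DH, with limma adjusted p of 0.00118, 0.0127 and 0.00249. Its Cy3 level went from 10.66 to 9.76 in Arc, from 10.68 to 10.11 in PAG and from 11.23 to 9.57 in DH, and its Cy5 level from 9.66 to 9.60, from 9.71 to 9.67 and from 10.27 to 9.45, with SDs of 1.24 (Cy3) and 1.05 (Cy5) in DH at 24 h (n = 5). Arc and PAG shared 392 rising and 227 falling spots, where independent lists would share 108 and 73.3. Arc and DH shared 152 rising and 3 falling spots, against 17.5 and 6.68, and PAG and DH shared 178 and 17, against 31.1 and 13. Among all tested spots with 10 values, called or not, the arrays of 24 h and 1 h did not overlap in 10.6% in Arc, 12.6% in PAG and 6.06% in DH, where chance alone gives 0.794%. Counts fell by over 1.5 times without Arc replicate 1 at 1 h (933) or 4 at 24 h (1022), DH replicates 1 (237) or 2 (160) at 1 h and DH replicates 2 (163), 4 (228) or 5 (245) at 24 h, and without DH replicate 2 at 1 h 83 calls were higher and 77 lower.

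In most spots past 1.5-fold, the Cy5 channel moved more than the Cy3 channel. For the rising spots the median Cy3 change from 1 h to 24 h, against uncalled spots of like brightness, was -0.14 in Arc, -0.075 in PAG and -0.078 in DH. The median Cy5 change was -0.98, -0.86 and -0.996. For the falling spots the Cy5 medians were 0.70, 0.58 and 0.93 and the Cy3 medians -0.04, -0.13 and -0.17. The Cy5 change was the larger of the pair in 202 of 224 rising spots in Arc, 429 of 545 in PAG and 104 of 130 in DH. No day held arrays of both times, so time and day cannot be told apart, and with day as a random block the calls numbered 419 in Arc, 1690 in PAG and 94 in DH. With a separate pool for each group, given a spread, limma called 0 spots in Arc (1602 at an unadjusted p below 0.05), 672 in PAG and 18 in DH, of which 1 was higher.

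The balance of directions between the times depended on the scaling. In PAG 1244 calls were higher and 1421 lower with median centring, and 1477 and 1685 in the authors' value table. In Arc 71.1% of calls were higher with median centring, against 56%, and 384 were higher and 450 lower with a loess within print blocks. In DH median centring gave 151 calls, 53% of them higher, against 67.4%. With separate pools Sr01Sc01R14C06 had a limma adjusted p of 0.102 in Arc, 0.00762 in PAG and 0.274 in DH, Sr06Sc03R14C06 of 0.0997 in Arc and 0.0296 in PAG, and Sr11Sc02R12C12 of 0.102 in Arc.

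**Figure D3:**
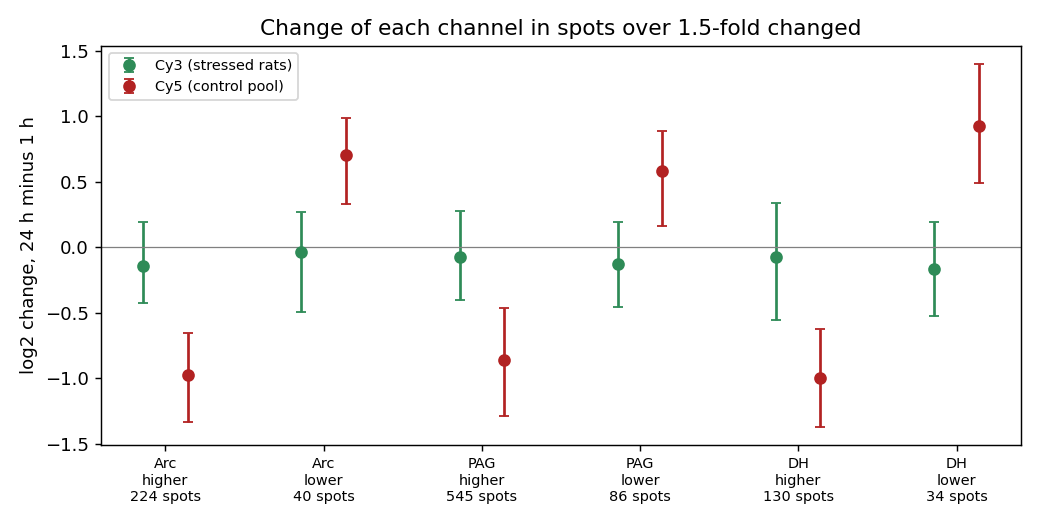
Points are the median log2 change from 1 h to 24 h of the Cy3 channel (stressed rats) and the Cy5 channel (control pool) in called spots over 1.5-fold higher or lower at 24 h, against uncalled spots of like brightness, and bars span the quartiles. Cy3 medians lay between -0.17 and -0.04, while Cy5 medians lay between -0.996 and -0.86 for rising and between 0.58 and 0.93 for falling spots.

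Differences between the regions were tested at each time. At 1 h 391 spots differed by limma's F test. Each of them was assigned to 1 region as the one standing apart, which is not a test. This was DH in 285 of them, above in 136 and below in 149. The 6 spots with the lowest p had limma adjusted p of 0.00526 to 0.00647. By pairs, 407 spots differed between DH and Arc and 189 between DH and PAG. The 189 are fewer than the 285, so the pair tests did not part DH from both other regions in all of these. Between PAG and Arc limma called 0, with 833 spots at an unadjusted p below 0.05, and 0 with the replicate number as a block, with 944. Per the labels the regions came from the same rats. Within day A, with 5 Arc and 3 PAG arrays, 28 spots differed between PAG and Arc, and within day B, with 2 PAG and 5 DH arrays, 15 differed between DH and PAG. With day as a fixed block limma called 26 spots between the 3 regions and as a random block 6, with a loess within print blocks 56, and it called fewer by over 1.5 times without Arc replicates 1 (211), 2 (221) or 3 (199) or DH replicates 1 (57), 2 (214), 3 (177) or 5 (186). Each region had a pool of its own, and with a spread given to each pool limma called 0 spots (608 at an unadjusted p below 0.05).

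At 24 h 1807 spots differed between the regions. By the same assignment, without a test, PAG stood apart in 1058 of them, Arc in 617 and DH in 132. By pairs, limma called 2240 spots between PAG and Arc, 463 between DH and PAG and 111 between DH and Arc. With 463 calls between DH and PAG, the pair tests did not part PAG from both other regions in all of the 1058. The lowest adjusted p, 3.42e-22 by limma, belonged to Sr02Sc01R11C06, at 0.27 in Arc, 0.13 in PAG and -4.35 in DH, and the 6 lowest reached up to 4.45e-13. Each of those 6 was low in DH, at -4.35 to -1.79. Their median Cy5 level was 10.59 in DH at 24 h and 7.61 in DH at 1 h, while the median Cy3 level was 7.62 and 7.61. All 6 were above background in Cy5 on the 5 DH arrays of 24 h and 4 in Cy3, against 2 in Cy5 on the 5 DH arrays of 1 h and 2 on the 5 PAG arrays of 24 h, so several ratios rest on signals near the background. Within day E, with 5 PAG and 2 DH arrays, 138 spots differed between DH and PAG, and the 463 called over all arrays had the same sign there in 100% of cases. All 5 PAG arrays and 2 of the 5 DH arrays were the same in both comparisons. The shared sign was therefore nearly fixed in advance and does not test an effect of day. The Arc arrays at 24 h shared no day with the other regions. With day as a random block limma called 738 spots, and with a spread given to the pool of each region 44. Without PAG replicate 2 or 3 the count was 1147 or 1140.

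The change from 1 h to 24 h differed between the regions at 1066 spots by limma's F test of the interaction. By the same assignment, PAG stood apart in 427 of them, DH in 357 and Arc in 282. Sr02Sc01R11C06 again had the lowest limma adjusted p, 8.58e-18, with a change of -4.29 ± 0.15 (SE) in DH, 0.40 ± 0.15 in Arc and 0.24 ± 0.15 in PAG. The Arc change leans on replicate 2 at 24 h, at 0.86 against 0.03 to 0.20 in the other arrays. The spot was above background in both channels on 3 of 5 arrays in Arc and PAG at 24 h and in DH at 1 h. Spot Sr01Sc01R14C06, whose ratio was higher at 24 h in the 3 regions, had an interaction adjusted p of 0.68 by limma. With median centring limma called 1848 spots, with day as a random block 349 and with a separate pool for each group, given a spread, 13.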

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

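The region and interaction tests and the fits without 1 array were fixed before the data were examined, and the tests of the rats, channels, control pools, print blocks and quantification day and the splits were chosen after the results were seen. Each result is listed because a sample lay far from the other 4 of its group or because a test found the regions to differ. Of 66 groups of 5 examined for a distant sample 5 stood out, where chance gives about 3.3, and 3 of the 5 belong to a spot picked for its differences between replicate numbers.

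PAG at 24 h replicate 4 had a median Cy5 signal of 905 units, against 545 to 600 in the other 4 arrays. Spot Sr02Sc01R11C06 had a log2 ratio of 0.86 in Arc at 24 h replicate 2, against 0.03 to 0.20 in the others. Spot Sr04Sc01R06C11, chosen after its values were seen, was distant in the same replicate number of all 3 regions at 1 h. Replicate 1 had log2 ratios of 0.83 in Arc, 1.22 in PAG and 1.69 in DH, and the other 4 rats of each region lay between -1.84 and -1.59, between -2.18 and -1.33 and between -1.94 and -1.27.

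The regions differed at 391 spots at 1 h, at 1807 spots at 24 h and in the change between the times at 1066 spots by limma. For each of these counts, and for the 3 comparisons of 24 h with 1 h, 1 of 100 splits of the same arrays, the real one, gave as many calls, so random divisions of the arrays rarely reach these counts. The highest other splits gave 6, 314 and 26 calls for the region tests. For the times they gave 356 in Arc (real 1540), 1464 in PAG (2844) and 96 in DH (368). The splits hold no measure of the spread between control pools. For the times the real split also parts the quantification days, so the splits cannot tell time from day. The region and interaction splits share this limit in part. At 1 h all Arc arrays were of day A and all DH arrays of day B. At 24 h the Arc arrays shared no day with the other regions. The splits of the regions at 1 h and at 24 h moved arrays between regions without regard to replicate number.

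The first pattern weighed is the rise over 1.5-fold from 1 h to 24 h. A change in the stressed rats' own RNA requires a Cy3 rise of about the change of the ratio (medians 0.79 in Arc, 0.78 in PAG and 0.94 in DH). The median Cy3 changes were -0.14, -0.075 and -0.078, with SDs over spots of 0.56, 0.60 and 0.73. This argues against it for these spots as a set only if the slides of both times gave these spots like signal. Lower signal in both channels of these spots on the 24 h slides would hide a Cy3 rise, and this was not tested. If the 271 spots that differ between replicate numbers vary between rats, which the labels do not settle, control RNA of other rats at the 2 times predicts larger Cy5 changes there. Their median Cy5 change in size was 0.65 in Arc, 0.91 in PAG and 0.53 in DH, each at percentile 100 of 10000 random lists matched on brightness (highest list 0.46, 0.53 and 0.35), and their Cy3 changes were also large, at percentiles 98, 100 and 100, so different control pools stay open, as do spots that vary in both channels for another reason. Cy5 labelling or slides particular to each time cannot be told apart from it, because 0 of the 6 days held arrays of both times.

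The second pattern is that 271 spots differed between replicate numbers of one time, by limma's F test at an adjusted p below 0.05. The effects of the numbers were fitted jointly over the 3 regions, and agreement in each single region was not tested. Of 100 draws of the numbers within groups, the real one alone gave as many, and the highest other gave 15. With the means of each group and day fitted, 148 spots passed, against at most 54 in draws within group and day, which argues against quantification day as the whole cause. That test replaced an earlier one on the Arc and DH arrays of 1 h alone, which share no day and gave 2 spots, a count that 10 of 100 draws reached with the real one included (highest other 2), so it did not exclude chance. No biological explanation was tested, as the design does not group the rats of one time, and individual rats or steps shared by all tissues of a rat may underlie these 148 spots.

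The third pattern is the count of 391 spots that differed between regions at 1 h. Print block explained 23.7% of the variance of the Arc effects at 1 h, 15% in PAG and 6.45% in DH. The shares were 24.3% for Arc at 24 h against 1 h and 16% for Arc at 24 h against the pool. A loess within blocks left 56 calls, and the median range between region means of the 391 spots went from 0.46 to 0.34 while the median SD between rats went from 0.16 to 0.15, so trends over print blocks may account for part of the count. A fixed effect of day left 26, but leaving out 1 DH array also left 57, so day cannot be told apart from the loss of precision. All Arc arrays of 1 h fell on day A and all DH arrays of 1 h on day B. Within PAG at 1 h, limma called 20 spots between the arrays of day B and of day A. A further 1676 is the count at an unadjusted p below 0.05. Between the days of Arc at 24 h the counts were 13 and 959, and for DH at 24 h 0 and 1227. Each day held other rats, so day was not separated from rats. A difference between the tissues, between their control pools or between days stays open.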

How the results depend on the processing

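The loess within print blocks, day as a fixed block and a separate pool for each group were chosen after the data were examined. Counts of called spots came from limma at an adjusted p below 0.05. Of 109 counts under settings other than leaving out a replicate, 79 stayed within 1.5 times the main count and 30 did not. Aquantile left the log ratios as they were by construction, no background subtraction and no filter on dim spots moved no count past 1.5 times, and signal over background left 23 spots to filter.

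Outside that range were, with the pool given a spread, 4, 37 and 288 spots at 1 h (Arc, PAG, DH; main 1158, 1190 and 1919) and 1508, 2616 and 398 at 24 h (main 4081, 4984 and 2171). With a spread for a separate pool of each group limma called 0 (1602 unadjusted), 672 and 18 for 24 h against 1 h, 0 (608 unadjusted) and 44 for the regions at 1 h and 24 h, and 13 for the interaction. Both follow from the larger standard error alone. With day as a random block (consensus correlation 0.106) the counts were 200, 541 and 765 at 1 h, 1435 for DH at 24 h, 419, 1690 and 94 for 24 h against 1 h (main 1540, 2844 and 368), 6 for the regions at 1 h, 738 at 24 h and 349 for the interaction (main 391, 1807 and 1066). Median centring gave 151 for DH at 24 h against 1 h and 1848 for the interaction. The authors' value table gave 1768 for Arc and 1826 for PAG at 1 h. The loess within print blocks gave 619 for Arc at 1 h, 834 for Arc at 24 h against 1 h and 56 for the regions at 1 h, and the fixed block of day gave 26 for the latter. Apart from the enlarged standard error, the cause was not tested.

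Leaving out 1 array at a time gave ranges of 526 to 1018 for Arc, 561 to 1103 for PAG and 1144 to 1574 for DH at 1 h, and 3154 to 4008, 4050 to 4763 and 1364 to 2035 at 24 h. For 24 h against 1 h they were 933 to 1586, 2253 to 3021 and 160 to 410, for the regions 57 to 543 at 1 h and 1140 to 1950 at 24 h, and for the interaction 756 to 1303. Counts fell by over 1.5 times in 24 of 120 such fits. These left out, against the pool at 1 h, Arc replicates 1 (562), 2 (526) and 4 (650), PAG replicates 1 (600) and 2 (561) and DH replicates 3 (1144) and 5 (1266), and at 24 h DH replicate 2 (1364). For 24 h against 1 h they left out Arc 1 h replicate 1 (933), Arc 24 h replicate 4 (1022), DH 1 h replicates 1 (237) and 2 (160) and DH 24 h replicates 2 (163), 4 (228) and 5 (245). For the regions at 1 h they left out Arc replicates 1 (211), 2 (221) and 3 (199) and DH replicates 1 (57), 2 (214), 3 (177) and 5 (186), and at 24 h PAG replicates 2 (1147) and 3 (1140).

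The 4 printed spots kept their direction in all 231 refits of the comparisons that name them and their side of the threshold in 227. The other 4 were those for 24 h against 1 h with separate pools, Sr01Sc01R14C06 in Arc (adjusted p 0.102) and DH (0.274) and, in Arc, Sr06Sc03R14C06 (0.0997) and Sr11Sc02R12C12 (0.102). The enlarged standard errors, Aquantile and no filter on dim spots leave the log ratios unchanged, so the direction could not turn in those refits. The printed spots were also picked from the extremes of the lists.

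Replicate numbers were tried as a block. Outside Arc and PAG at 1 h, at most 4 of 5 same-numbered pairs correlated over 0.1, so numbers were not taken as pairs in the 3-region tests. As a hint from the data, at most 9 of 10 arrays of a pair of groups correlated best with their own number. The block moved no count past 1.5 times (496 and 2092 for the regions at 1 h and 24 h, 1296 for the interaction, and 1379, 2717 and 313 for the times). Gene list tests with camera were not run because the spots have no gene names.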

Other observations

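The values in this part were chosen after the data were examined.

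Of the 173 spots called higher in all 3 regions at 1 h, 138 were called higher in Arc at 24 h, 111 in PAG and 70 in DH, with median log2 ratios of 0.42, 0.27 and 0.21 at 24 h, against 0.36, 0.37 and 0.39 at 1 h. Among all 12183 tested spots 2074, 2615 and 1216 were called higher at 24 h. A dye bias, or a pool shared by the times, would also give such an overlap. The effects in DH at 1 h correlated across spots at 0.515 with those in Arc at 24 h, higher than at 0.373 with those in Arc at 1 h, and the difference between these correlations was not tested. DH at 1 h and Arc at 24 h shared 698 higher and 447 lower spots, where independent lists would share 189 and 133.

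Of the 26 spots that fell over 1.5-fold in DH at 24 h, 23 lay in rows 11 to 16 of their print blocks, which hold 37.1% of all tested spots. Of the same 26 spots 3 were called lower and 3 higher in Arc at 24 h, and 3 lower and 4 higher in PAG at 24 h. The range of positions was picked after their places were seen, so it was not tested. The 6 highest spots of 24 h against 1 h in Arc, Sr01Sc01R14C06 among them, also lay in rows 11 to 16. Most of the 6 highest in PAG and in DH did too. The 8 lowest spots of Arc at 24 h had a median of -1.34 there, of -0.12 in PAG and of -0.15 in DH at 24 h, and of -0.27 in Arc, -0.49 in PAG and -0.24 in DH at 1 h. Most of these 8 lay in row 3 of blocks in the first block column, and their SDs in Arc at 24 h reached 1.64. A fall particular to Arc was therefore not separated from position on the array.

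At 24 h spot Sr04Sc01R06C11 was high in 2 replicate numbers of each region. Replicates 1 and 4 had log2 ratios of 4.15 and 4.21 in Arc, 4.04 and 4.12 in PAG and 3.43 and 3.08 in DH, and the other 3 rats lay between -0.31 and 0.93. Its mean Cy5 level was 11.24, 11.52 and 10.49 on the Arc, PAG and DH arrays at 1 h, and 8.70, 9.13 and 8.48 at 24 h. In another spot, in a different print block and also chosen after its values were seen, the same replicates led in 5 of the 6 groups, and in the remaining group 1 of the 2 had no usable value.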
